A study of Homo sapiens with 6 samples.

How the data were processed

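RNA of T24 cells was sequenced in 6 libraries, 3 labelled shControl and 3 labelled shCCDC137. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by a standard Illumina procedure. The deposited table holds raw read counts per gene for all 6 libraries, in whole numbers that were not normalized. Per the submitters' processing notes, fastp 0.20.1, HISAT2, StringTie 2.0.4 and the GRCh38 genome were used; the version of HISAT2, the counting tool, the annotation release and the use of strand are not given in the sources used here. The table has 22486 rows, of which 20474 carry an Ensembl gene identifier and 2012 are loci assembled by StringTie without one. The assembled loci took 1.43% to 1.48% of each library's counts and stayed in the tests. 29 gene symbols stand on more than 1 row, and such rows were kept apart by identifier. Transcript lengths, GC content, 3′ UTRs and gene positions came from GENCODE 29, which matched 20242 of the Ensembl rows. Length and GC content are those of the longest annotated transcript of each gene, which need not be the one expressed.

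Each column was assigned to its sample by the library name in the labels, and each sample to its group by its title. Library totals ran from 31269820 to 37109646 counts, the smallest being 84.3% of the largest. Libraries of 1 group differed from each other by more than counting noise (chi-square per degree of freedom 10.3 to 13.1 over the 6 pairs), so none was treated as a second copy of another, and libraries of different groups differed more (57.5 to 75.7 over the 9 pairs). The first principal component, with 35.8% of the variance, separated the groups.

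Counts were filtered with filterByExpr (minimum count 10), which kept 14637 rows, 13341 of them Ensembl genes. Library sizes were taken over the rows kept and scaled by the trimmed mean of M-values (factors 0.994 to 1.008), and the counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest) with group as the only term. The test is two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.188, its median over genes was 0.0989, and the prior had 2.96 degrees of freedom. CPM values are given as mean ± SD over 3 libraries with the scaling factors applied, and the SE of a log2 fold change is its size divided by the square root of F. The median SE over all genes tested was 0.073.

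The genes named in the text follow a rule set before the data were examined: CCDC137, then the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 CPM, a gene symbol and groups that do not overlap, then up to 4 members of each described list with the smallest adjusted p. Some genes that the rule picks are not reported here. Genes outside the rule, named after their values were seen, are OXLD1 as a neighbour of CCDC137, IL33 for its part in a mean, and those marked in the closing section. The 45 gene lists were also set before the data were examined, from general knowledge of the pathways. The 42 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists) on log2 CPM. The same test with the correlation estimated per list, and fry, a rotation test of each list on its own, were run beside it.

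The procedure was tested on simulated counts for the 14637 genes with the means and library sizes of this comparison. Of 50 genes each changed by 0.25, 0.5, 1 and 2 on the log2 scale, 10%, 50%, 64% and 88% were recovered with the right sign. Of the calls made, 4.50% were false, and 1 gene was called when none was changed. A list shifted by 0.3 was recovered and 0 other lists were called. The simulated genes were drawn independently of each other, so this does not give the rate of false list calls in these data. The simulation changed 200 genes, while 6803 passed in the data, and the adjustment is stricter where fewer genes change. The shares recovered therefore do not carry over to this comparison. How often a small change was missed here was not measured.

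Alternatives set before the data were examined were 3 other scalings, 2 other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and a test against a log2 fold change of 1 (glmTreat). Alternatives added after seeing the data were Ensembl rows alone, per-library offsets from a smooth fit on transcript length and GC content (13256 genes), the counts without the 13 mitochondrially encoded genes, and a robust prior. Fold changes were also compared with 7-base sequences in the 3′ UTRs of 12003 genes and with gene position, in 10000 rotations of the fold changes along the genome. In the scan's own test, on permuted fold changes, a sequence with a planted effect of 0.15 was ranked 1. The sequence most strongly linked to lower values in the data had a mean difference of -0.0512 on the log2 scale. A planted effect that small was not tried. Genes with no annotated 3′ UTR, or one not searched (2634 of those tested), stayed out of that scan. The short hairpin sequences, protein levels and DNA copy number were not analysed here.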

Results

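The transcriptome of T24 cells, an established line from a human urinary bladder transitional cell carcinoma, was measured by RNA sequencing in 6 libraries. The 3 shControl libraries came from cells with a control short hairpin RNA, and the 3 shCCDC137 libraries from cells with a short hairpin RNA against CCDC137. A short hairpin RNA is processed in the cell into a small RNA that lowers the level of transcripts it pairs with. The question was how gene expression differs between CCDC137 knockdown and control cells. The total count over all genes was 35999234, 35889847 and 36025430 in shControl replicates 1, 2 and 3, and 37109646, 36577533 and 31269820 in shCCDC137 replicates 1, 2 and 3. Mitochondrially encoded genes took 3.07% to 3.29% of the counts in the shControl libraries and 3.81% to 4.30% in the shCCDC137 libraries. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

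CCDC137 was lower in the shCCDC137 libraries, by a modest amount. The gene (ENSG00000185298, chromosome 17, 81666364 to 81673904 on the plus strand of GRCh38) encodes a coiled-coil protein of the nucleolus and of the surface of mitotic chromosomes. Its level was 109.8 ± 2.33 CPM (counts scaled to a common library size; SD, n = 3) in shControl and 87.3 ± 3.65 CPM (SD, n = 3) in shCCDC137. It fell by 20.5%, a log2 fold change of -0.33 (SE 0.036), with an adjusted p of 4.0e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Single libraries held 3898, 3890 and 4049 counts of CCDC137 in shControl and 3375, 3119 and 2687 in shCCDC137, and every shCCDC137 library lay below every shControl library in CPM. Among the genes that fell, 1801 fell by more than CCDC137 on the log2 scale. OXLD1, which lies on the minus strand and overlaps the first 272 bases of CCDC137, rose with a log2 fold change of 0.35 (adjusted p 0.012 by edgeR). The use of strand in counting is not given in the sources used here, so reads of this shared stretch cannot be assigned with certainty.

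**Figure D1:**
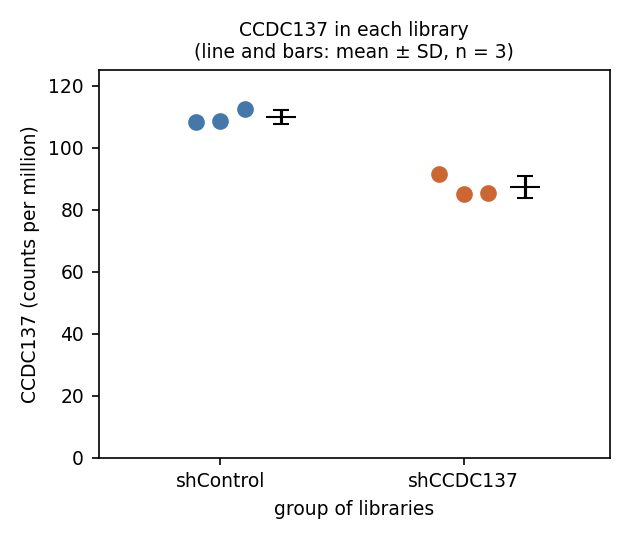
CCDC137 level in CPM (vertical axis, from 0) in each of the 3 shControl and 3 shCCDC137 libraries, with the mean and SD of each group beside the points. The shControl libraries lie between 108 and 113 CPM and the shCCDC137 libraries between 85.2 and 91.6 CPM.

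The genes named by the size of their rise included SERPINB2, IL24 and THBD. SERPINB2, an inhibitor of plasminogen activators (chromosome 18, 63871692 to 63903890), had the largest rise of the 12 genes named for a rise, which have a gene symbol and a mean of at least 5 CPM, from 5.16 ± 0.808 to 220.0 ± 6.86 CPM (log2 fold change 5.41, SE 0.091, adjusted p 2.6e-07 by edgeR). IL24, a cytokine of the IL-10 family (chromosome 1, 206897443 to 206904139), rose from 1.20 ± 0.191 to 21.5 ± 0.401 CPM (log2 fold change 4.16, SE 0.13). THBD, the thrombin receptor thrombomodulin (chromosome 20, 23045633 to 23049741), rose from 3.11 ± 0.219 to 45.7 ± 1.25 CPM (log2 fold change 3.88, SE 0.074). FST, which binds activins, rose from 30.5 ± 0.359 to 127.9 ± 3.69 CPM (log2 fold change 2.07), and the stress cytokine GDF15 rose from 5.28 ± 0.0994 to 23.3 ± 0.661 CPM (log2 fold change 2.14). The other large rises were in ANKRD1 (3.74 on the log2 scale), EPB41L3 (3.37), the protease inhibitor SLPI (2.95), RAB39B (2.90), the transporter SLC16A6 (2.47), MAL2 (2.44) and SH3TC1 (2.09). ANKRD1 and EPB41L3 were each under 1 CPM on average in shControl, which leaves their fold changes less precise (SE 0.32 for both).

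The 12 genes named by the size of their fall, under the same rule, included SCD, EFNA1 and EGR1. SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids (chromosome 10, 100347124 to 100364834), fell from 557.7 ± 3.27 to 96.9 ± 4.85 CPM (log2 fold change -2.52, SE 0.039, adjusted p 2.0e-07 by edgeR). EFNA1, a ligand of Eph receptors, fell from 52.3 ± 1.05 to 9.11 ± 1.06 CPM (-2.52), and the cholesterol exporter ABCA1 from 23.4 ± 1.10 to 4.77 ± 0.847 CPM (-2.29). The transcription factor gene EGR1 (chromosome 5, 138465490 to 138469315) fell from 438.8 ± 16.6 to 99.3 ± 1.19 CPM (-2.14, SE 0.034). CCN2, which encodes a matricellular growth factor (chromosome 6, 131948176 to 131951373), fell from 398.2 ± 1.45 to 109.9 ± 0.309 CPM (-1.86, SE 0.021). The log2 fold changes were -1.85 for CD69, -1.82 for FOSB, -1.81 for the NOTCH-responsive repressor HES1, -1.74 for the kinase SGK1, -1.63 for the sterol sensor INSIG1, -1.61 for FOS and -1.55 for thrombospondin 1 (THBS1). For each of these 24 genes the 3 shCCDC137 libraries lay on the same side of the 3 shControl libraries, as the rule for naming them required. The adjusted p by edgeR was at most 3.2e-04.

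**Figure D2:**
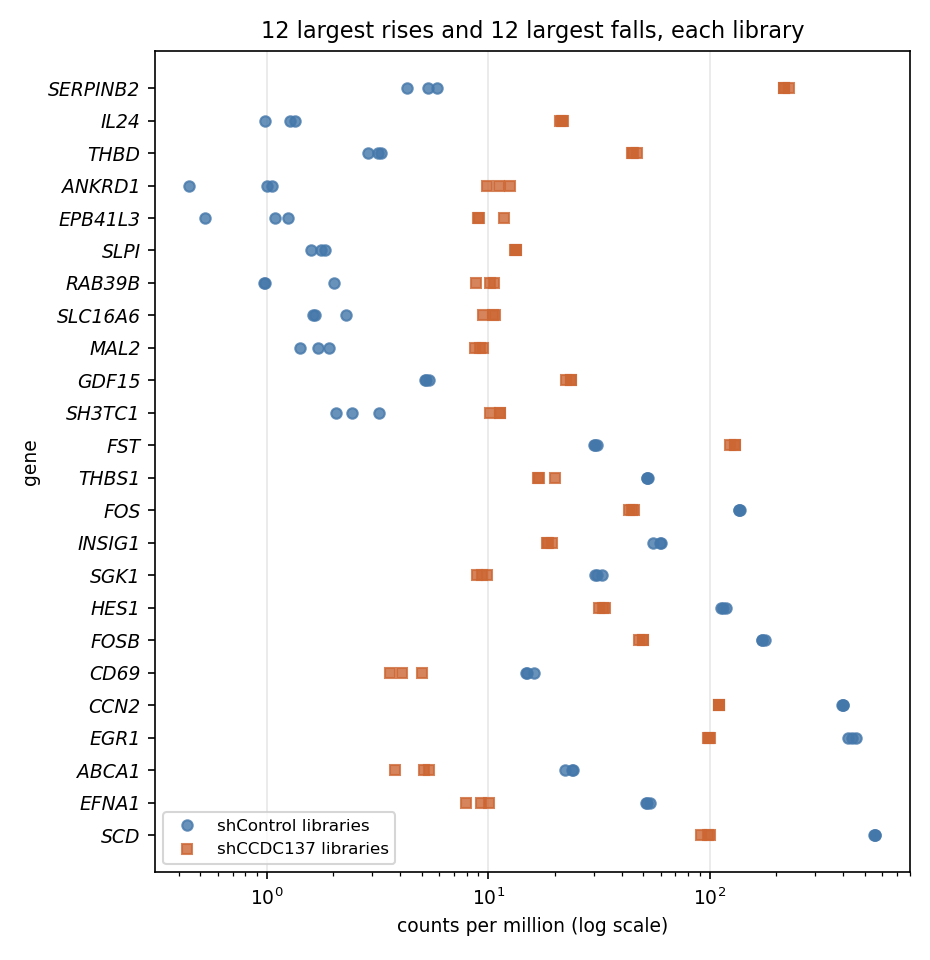
Level of each of the 24 genes in CPM on a log axis, each point a library, with shControl as circles and shCCDC137 as squares. By the rule for naming them, the groups do not overlap for any of these genes, from SERPINB2 (log2 fold change 5.41) at the top to SCD (-2.52) at the bottom.

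The difference between the groups reached far beyond these genes. Of 14637 genes tested, 6803 (46.5%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3416 higher and 3387 lower in shCCDC137, and 7786 had an unadjusted p under 0.05. Most of the changes were small: the median size was 0.34 on the log2 scale, and 521 genes had a log2 fold change of at least 1 in size, 323 higher and 198 lower. When the test itself was set against a log2 fold change of 1, 109 genes passed. The groups did not overlap in 8432 genes (57.6%), where chance gives 10% for 3 libraries against 3. Across genes, which are not independent replicates, the log2 fold change ran lower with longer transcripts (Spearman's rho -0.24) and higher with GC content (rho 0.26) over the 13256 genes with an annotated transcript.

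Genes of the integrated stress response, the program of amino acid synthesis and stress signalling driven by the factor ATF4, rose together. Of 39 members tested, 30 were higher and 2 lower (31 and 2 adjusted over the list alone), with a median log2 fold change of 0.40 and an adjusted p of 1.5e-09 by camera, a test of a list against all other genes. The adjusted p was 0.054 with an estimated correlation. Asparagine synthetase (ASNS) rose from 60.7 ± 0.598 to 141.7 ± 1.07 CPM (log2 fold change 1.22), STC2 from 221.4 ± 4.13 to 548.5 ± 19.7 CPM (1.31), and the serine synthesis enzyme PSAT1 from 261.1 ± 3.49 to 408.4 ± 7.98 CPM (0.65), beside GDF15. Chaperones of the endoplasmic reticulum, another stress program, did not pass as a list: 9 of 30 members were higher and 6 lower, the same adjusted over the list alone, with an adjusted p of 0.67 by camera.

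Genes for making ribosomes and for respiration were also higher as groups. The list of ribosome biogenesis and nucleolar factors had 40 of 58 members higher and 2 lower (42 and 3 adjusted over the list alone), a median of 0.25 and an adjusted p of 9.2e-08 by camera, which was 0.048 with an estimated correlation. Its leading members were RRS1 (67.8 ± 0.788 to 102.8 ± 1.32 CPM, log2 fold change 0.60), RRP12 (0.49), MYBBP1A (0.50) and RRP1B (0.41). Cytosolic ribosomal proteins had 66 of 75 members higher and 0 lower (69 and 0 adjusted over the list alone), a median of 0.27 and an adjusted p of 5.8e-15, which rose to an adjusted p of 0.28 with an estimated correlation. RPL13A (0.41), RPLP0 (0.30) and RPL3 (0.28) were among those leading that list, and since ribosomal protein genes share sequence with many processed pseudogenes, their single values are uncertain. MYC targets had 17 of 28 members higher and 1 lower, with the same counts adjusted over the list alone, a median of 0.18 and an adjusted p of 3.9e-04 by camera (adjusted p 0.067 with an estimated correlation), led by ODC1 (0.80), SRM (0.58), EIF4EBP1 (0.42) and MTHFD2 (0.40). Nuclear-encoded respiratory chain genes had 36 of 60 members higher and 3 lower (39 and 3 adjusted over the list alone), a median of 0.23 and an adjusted p of 8.6e-07 (adjusted p 0.26 with an estimated correlation), led by COX6A1 (0.46), COX6C (0.53), COX4I1 (0.33) and UQCRH (0.47). The 13 mitochondrially encoded genes had 11 higher and 0 lower (12 and 0 adjusted over the list alone), a median of 0.28 and an adjusted p of 0.0014 (adjusted p 0.49 with an estimated correlation), with MT-CO1 at 8430 ± 195 CPM in shControl and 11068 ± 360 CPM in shCCDC137, and their share of all counts was larger in every shCCDC137 library, as given above. After a correction for transcript length and GC content, chosen after seeing the data, the mitochondrially encoded list had a median of 0.17 and no longer passed (adjusted p 0.066, in a range of 2.5e-04 to 0.066 over the alternatives other than the estimated correlation and fry).

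Lysosomal and interferon-stimulated genes also rose as lists. Of 40 autophagy and lysosome genes 20 were higher and 3 lower (23 and 4 adjusted over the list alone), with a median of 0.14 and an adjusted p of 0.0011 by camera (adjusted p 0.067 with an estimated correlation). The lysosomal enzymes CTSA (0.55), HEXA (0.53) and CTSD (0.43) and the proton pump subunit ATP6V0D1 (0.48) led it. Of 39 genes of the type I interferon response 18 were higher and 7 lower, with the same counts adjusted over the list alone, a median of 0.23 and an adjusted p of 0.029 (adjusted p 0.25 with an estimated correlation). The antiviral genes IFIT2 (33.3 ± 0.207 to 83.8 ± 3.41 CPM, log2 fold change 1.33), OASL (1.84) and ISG15 (0.95) rose, while PARP14 fell (-0.76). Without shCCDC137 replicate 2 the interferon list had an adjusted p of 0.0507, in a range of 0.0015 to 0.0507 over the alternatives other than the estimated correlation and fry.

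Genes of cell division were lower. In the list for mitosis and the G2/M phase, 39 of 43 members were lower and 0 higher, with the same counts adjusted over the list alone, a median of -0.40 and an adjusted p of 8.4e-14 by camera, which was 0.048 with an estimated correlation. The kinetochore proteins CENPF (282.5 ± 4.83 to 166.5 ± 0.534 CPM, log2 fold change -0.76) and CENPE (-0.73), the cytokinesis kinesin KIF20A (-0.73) and the centrosomal kinase NEK2 (-1.02) led the list. DNA repair and damage signalling genes had 29 of 42 members lower and 0 higher (30 and 0 adjusted over the list alone), a median of -0.22 and an adjusted p of 3.0e-07 (adjusted p 0.14 with an estimated correlation), with BRCA1 at -0.67, MRE11 at -0.48, ATR at -0.45 and H2AX at -0.43. DNA replication genes and E2F targets were also lower as a list, with 22 of 43 lower and 5 higher, the same counts adjusted over the list alone, a median of -0.13 and an adjusted p of 0.0089 (adjusted p 0.10 with an estimated correlation). RFC5 (-0.59), TK1 (-0.50), TYMS (-0.43) and RRM2 (-0.38) were its leading members. Replication-dependent histones did not pass, with 2 of 19 higher and 1 lower (0 and 0 adjusted over the list alone) and an adjusted p of 0.86.

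Genes of the extracellular matrix and of the pathways that induce it were lower. The mesenchymal and extracellular matrix list had 23 of 33 members lower and 5 higher, with the same counts adjusted over the list alone, a median of -0.38 and an adjusted p of 1.7e-06 by camera (adjusted p 0.054 with an estimated correlation). Fibronectin (FN1) fell from 4085 ± 58.4 to 1629 ± 55.6 CPM (log2 fold change -1.33) and CCN1 from 809.4 ± 3.09 to 328.7 ± 9.89 CPM (-1.30), beside CCN2. TGF-beta response genes had 13 of 25 lower and 3 higher, again the same adjusted over the list alone, with a median of -0.21 and an adjusted p of 0.0041 (adjusted p 0.10 with an estimated correlation). LTBP2 (-1.07) and BHLHE40 (-1.22) were among its leading members, together with CCN2. Targets of YAP and TEAD, the effectors of the Hippo pathway, had 16 of 26 lower and 4 higher, the same adjusted over the list alone, with a median of -0.22 and an adjusted p of 0.0048 (adjusted p 0.26 with an estimated correlation), led by CCN2, CCN1, AXL (-0.42) and F3 (-0.47), while ANKRD1, a target in the same list, rose by 3.74. After the correction for length and GC content the YAP and TEAD list passed at the preset correlation (adjusted p 0.019), with a median of -0.11; over the alternatives other than the estimated correlation and fry, its adjusted p was 4.7e-10 to 0.019.

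Early response genes and inflammatory mediators were mostly lower. The list of AP-1 and immediate early genes, which are induced within minutes of stimulation, had 17 of 25 members lower and 4 higher (17 and 5 adjusted over the list alone), a median of -0.52 and an adjusted p of 3.1e-05 by camera (adjusted p 0.054 with an estimated correlation). JUN fell from 336.7 ± 2.41 to 171.2 ± 2.86 CPM (log2 fold change -0.98), beside FOS, FOSB and EGR1. Of 33 genes of the NF-kB and inflammatory cytokine list 19 were lower and 8 higher (20 and 9 adjusted over the list alone), with an adjusted p of 0.0098 toward lower values (adjusted p 0.16 with an estimated correlation). SOD2 (1324 ± 19.1 to 746.6 ± 14.5 CPM, log2 fold change -0.83), LIF (-0.79) and IL6 (147.2 ± 5.23 to 73.7 ± 0.762 CPM) fell, and IL24 rose. The signs of this list's summaries differed, with a median of -0.32 and a mean of 0.05, because the mean includes IL24 and IL33, and IL33 had 0 counts in all shControl libraries, so that its fitted fold change has no fixed size.

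Genes of sterol supply were lower. Of 25 genes of cholesterol biosynthesis and uptake 18 were lower and 2 higher (19 and 3 adjusted over the list alone), with a median of -0.28 and an adjusted p of 2.1e-05 by camera (adjusted p 0.054 with an estimated correlation). STARD4 fell by 0.79 on the log2 scale and IDI1 by 0.74, beside INSIG1. Fatty acid and lipid synthesis genes had 10 of 22 lower and 4 higher (12 and 4 adjusted over the list alone) and did not pass camera as a list (adjusted p 0.058; 2.1e-05 by fry, toward lower values), although FADS2 (113.2 ± 1.96 to 44.0 ± 1.15 CPM, log2 fold change -1.36), FADS1 (-0.53) and the sterol-regulated factor SREBF1 (-0.96) fell beside SCD.

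**Figure D3:**
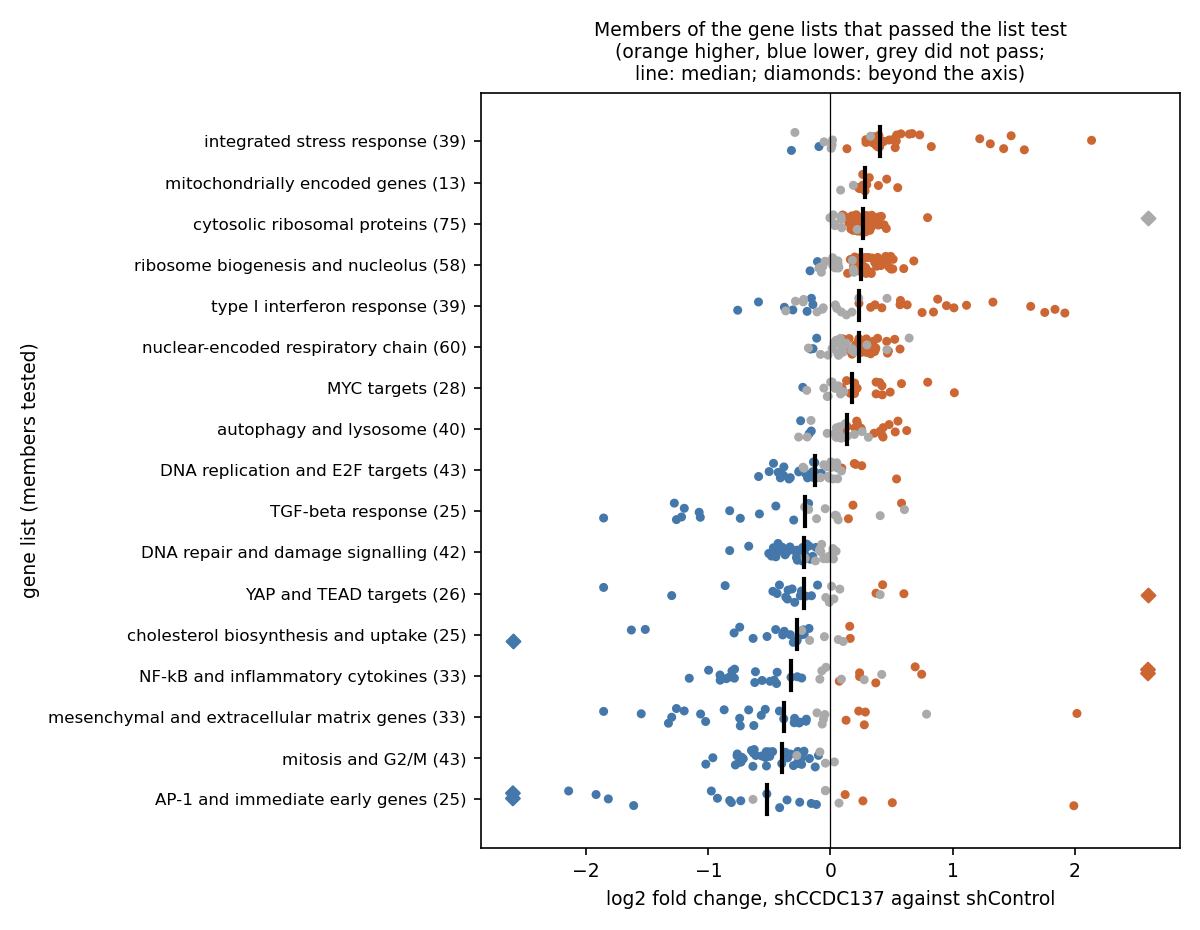
Log2 fold change of every tested member of the 17 gene lists that passed camera at an adjusted p of 0.05, 1 point per gene, ordered by the list median (black line), with higher genes in orange, lower genes in blue, genes that did not pass in grey and values beyond the axis as diamonds. Medians run from 0.40 for the integrated stress response to -0.52 for AP-1 and immediate early genes.

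In all, 17 of the 42 lists with at least 5 tested members passed camera with its preset correlation, 8 higher and 9 lower. With an estimated correlation 2 passed, mitosis and G2/M and ribosome biogenesis. Some lists that lost their call had an estimated correlation under the preset 0.01. Among them were MYC targets (-0.035), AP-1 and immediate early genes (-0.019), DNA replication and E2F targets (-0.009) and cholesterol genes (-0.003). For these the rise in adjusted p does not come from a larger correlation within the list, so a lost call is not by itself a sign of one. Over all 42 lists the lowest adjusted p by camera with an estimated correlation was 0.048. By fry, which tests whether a list's genes move on balance one way without comparing them with other genes, 34 lists passed, and 41 lists held changes in either direction.

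Other lists held many changed genes but did not pass camera with its preset correlation. By fry the RNA polymerase I and III, NOTCH, retinoic acid, hypoxia, heat shock, apoptosis and PI3K-AKT-FOXO lists passed, with adjusted p from 1.3e-05 for NOTCH response to 0.013 for hypoxia and glycolysis, and the p53 and spliceosome lists did not. p53 targets had 9 of 32 higher and 12 lower (adjusted p 0.58 by camera): AEN (0.67), SESN2 (1.42) and the cell cycle inhibitor CDKN1A (0.58) rose and APAF1 fell (-0.55). RNA polymerase I and III subunits had 16 of 33 higher and 5 lower (16 and 7 adjusted over the list alone), with an adjusted p of 0.053, and POLR3G (0.70) led them. NOTCH response genes had 6 of 12 lower and 1 higher (adjusted p 0.15), led by HES1 and NOTCH1 (-0.46). Retinoic acid response genes had 5 of 17 higher and 5 lower (adjusted p 0.66), with ALDH1A3 (0.43), TGM2 (0.33) and RBP4 (1.17) higher and RXRA lower (-0.30). Genes of hypoxia and glycolysis had 15 of 36 higher and 11 lower (adjusted p 0.67), and heat shock proteins 10 of 26 higher and 9 lower (adjusted p 0.67), with SERPINH1 (-0.64) and HSP90AA1 (-0.47) lower and HSPA8 (0.29) higher. Apoptosis regulators had 10 of 34 higher and 15 lower (11 and 15 adjusted over the list alone; adjusted p 0.37). PI3K-AKT-FOXO genes had 7 of 29 higher and 11 lower (7 and 12 adjusted over the list alone; adjusted p 0.35), led by SGK1 and PIK3CD (-0.49). Spliceosome genes had 7 of 42 higher and 12 lower (adjusted p 0.81), with HNRNPA2B1 (-0.37) leading. Where no second pair of counts is given in this paragraph, the counts adjusted over the list alone were the same. The median, the mean and the direction of camera differed in sign for the lists of hypoxia and glycolysis, heat shock proteins, spliceosome, epithelial junction, ferroptosis and senescence genes, none of which passed camera with its preset correlation; by fry the hypoxia (adjusted p 0.013), heat shock (0.0017) and senescence (4.2e-05) lists passed.

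Genes that mark epithelial state and immune visibility went both ways. Epithelial junction and urothelial genes had 5 of 21 higher and 7 lower, the same adjusted over the list alone (adjusted p 0.84 by camera), with the keratins KRT7 (-0.42) and KRT8 (-0.32) and the receptor ERBB3 (-1.34) lower and KLF5 (0.64) higher. Basal and squamous keratinocyte genes had 3 of 14 higher and 6 lower (5 and 6 adjusted over the list alone; adjusted p 0.69), with CD44 (-0.37) and DSC3 (-0.62) lower. Antigen presentation and immune checkpoint genes had 5 of 22 higher and 6 lower, the same adjusted over the list alone (adjusted p 0.66): the checkpoint ligand gene CD274 rose from 10.04 ± 1.22 to 19.6 ± 1.33 CPM (log2 fold change 0.97), while ERAP1 (-0.71), CD47 (-0.43) and TAPBP (-0.70) fell. By fry the basal and squamous list (adjusted p 0.0032) and the antigen presentation list (adjusted p 0.011) passed toward lower values, and the epithelial junction list did not (adjusted p 0.19).

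Markers of cell types that a bladder carcinoma line should not hold were few and mostly low, with exceptions in the leukocyte, neuronal and kidney lists. Of 15 fibroblast markers 2 passed the count filter, and both were lower, COL1A1 (6.38 ± 0.757 to 2.78 ± 0.318 CPM) and PDGFRB (2.73 ± 0.121 to 1.06 ± 0.467 CPM). Of 20 leukocyte markers 7 were tested, 3 were higher (LCP1, ITGAX and CD14) and 0 lower (adjusted p 0.13 by camera). LCP1 went from 20.7 ± 1.18 to 42.0 ± 1.21 CPM and ITGAX from 0.0278 ± 0.0278 to 0.485 ± 0.174 CPM. CD14 was at 1.30 ± 0.306 CPM in shCCDC137. The call of CD14 ended under 7 alternatives. Of 13 endothelial markers 4 were tested, and TIE1 (0.548 ± 0.0977 to 4.08 ± 0.262 CPM) and ROBO4 (3.23 ± 0.474 to 5.93 ± 0.540 CPM) were higher. Neuronal and glial markers had 4 of 6 tested members higher and 1 lower (adjusted p 0.27 by camera), and kidney line markers 1 of 6 higher and 2 lower (adjusted p 0.67). Their highest named members were not low: ENO2 went from 63.2 ± 0.693 to 91.6 ± 4.08 CPM and PAX8 from 549.5 ± 2.89 to 453.0 ± 6.32 CPM. By fry the leukocyte (adjusted p 0.0030) and neuronal (adjusted p 0.0024) lists passed toward higher values and the kidney list (adjusted p 0.034) toward lower values. Of the 23 snoRNA host genes in the list only TAF1D was tested, with a log2 fold change of -0.09 (adjusted p 0.065 by edgeR). Whether the others were missing from the count table or fell below the count filter was not examined, so nothing follows on their levels. Adjusted over the list alone, TAF1D and another endothelial marker, PECAM1, also passed, and the counts of the other marker lists were the same.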

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

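The correction for length and GC content, the Ensembl rows alone, the counts without mitochondrially encoded genes and the robust prior were chosen after seeing the data. CCDC137 was lower and passed under all 18 alternatives, with a log2 fold change of -0.31 to -0.37 when 1 library was left out and -0.44 after the correction for length and GC content. The count of genes that passed ran from 5789 to 6262 with 1 library left out and from 6478 to 7038 under the other alternatives apart from the block (DESeq2 6692, with 594 adjusted p not given; limma-voom 6951), against 6803, and all genes shared with the original calls had the same sign under each alternative except the length and GC correction, where 5339 of 5357 had. With a replicate block 6165 genes passed, of which 6011 were shared; it ended no list's call. The replicate numbers do not pair the libraries, since deviations from the group means correlated at -0.03, 0.06 and 0.04 between libraries of the same number, and 1 of the 3 shControl libraries correlated best with its own number.

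The test against a log2 fold change of 1 called 109 genes in place of 521; it asks for more than 1 beyond the error, which lowers the count by construction. The lists that passed numbered 2 with an estimated correlation and 34 by fry, against 17, and 16 to 21 under the other alternatives. After the length and GC correction the mitochondrially encoded list did not pass, with an adjusted p of 0.066 and a median of 0.17 (SD over members 0.140) in place of 0.28 (0.119). A smaller median and a wider spread both weigh against a call, and which of them ended it was not tested. Elsewhere, the estimated correlation and fry aside, its adjusted p was at most 0.0043. The RNA polymerase I and III list (adjusted p 0.039) and the fatty acid list (adjusted p 0.044) passed after that correction, and lay on both sides of 0.05 over the same alternatives (0.033 to 0.096 and 1.1e-09 to 0.085). With camera on DESeq2's test statistics 3 further lists passed: NOTCH response (adjusted p 0.0057, up to 0.21 elsewhere), NRF2 and antioxidant (0.0087, up to 0.44) and senescence genes (3.5e-04, up to 0.51). The interferon list had an adjusted p of 0.0015 to 0.0507 over the same alternatives, the highest without shCCDC137 replicate 2; the cause was not tested.

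Of the 25 genes named by size or as the target none lost its call. Calls ended under some alternative for 8 other named genes, among them H2AC11, H1-2 and CD14. After the length and GC correction H2BC12 turned from 0.26 to -0.023 (adjusted p 0.82; 0.015 to 0.068 elsewhere) and TAF1D from -0.09 to 0.10 (adjusted p 0.031, the lowest of a range up to 0.18); the cause was not tested.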

Other observations

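Genes of growth factor output and of matrix turnover, which the comparison above does not describe, changed in both directions. In the RAS-MAPK output list 12 of 25 members were higher and 5 lower (13 and 6 adjusted over the list alone; adjusted p 0.18 by camera). Cyclin D1 (CCND1) fell by 0.70 on the log2 scale, the ERK phosphatase DUSP6 by 0.97 and LIF by 0.79, while PHLDA1 rose by 0.44. All 4 ligands of the EGF receptor in that list, named after their values were seen, rose: AREG by 1.77 (6.96 to 23.7 CPM), HBEGF by 0.88, EREG by 0.74 and TGFA by 0.63, with adjusted p of at most 2.6e-04 by edgeR's quasi-likelihood test. Matrix proteases and inhibitors had 11 of 25 higher and 8 lower, the same adjusted over the list alone (adjusted p 0.67): PLAU (-0.53), ADAM10 (-0.61) and ADAM9 (-0.45) fell. WNT response genes had 6 of 23 higher and 9 lower (6 and 11 adjusted over the list alone; adjusted p 0.40), and passed fry toward lower values (adjusted p 4.5e-04), with CCND1 (-0.70) lower and the inhibitor DKK1 (0.88), the receptor FZD8 (0.84) and MYC (0.37) higher.

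Some antioxidant genes and genes of metal-binding proteins changed, although their lists did not pass camera with its preset correlation; both passed fry (adjusted p 2.8e-04 and 0.011). NRF2 and antioxidant genes had 13 of 29 higher and 6 lower (adjusted p 0.10 by camera): AKR1C1 rose from 8.14 ± 0.611 to 33.3 ± 0.363 CPM (log2 fold change 2.03), TXNRD1 by 0.50 and PGD by 0.58, while ABCC3 fell by 0.59. Ferroptosis regulators had 4 of 18 higher and 6 lower (4 and 7 adjusted over the list alone; adjusted p 0.84), with CHAC1 (1.59) and HMOX1 (0.81) higher and SAT1 (-0.90) and ACSL4 (-0.57) lower. Metallothioneins and zinc transporters had 1 of 9 higher and 4 lower (adjusted p 0.36), with MT2A at -0.47. Cell cycle inhibitors and senescence genes had 8 of 23 higher and 11 lower (adjusted p 0.37), with GDF15 (2.14) higher and RBL2 (-0.65) lower. Except for ferroptosis regulators, the counts of these lists adjusted over the list alone were the same.

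In the patterns weighed next, the tests of scaling, of a control library among the shCCDC137 libraries and of the splits of the libraries, and the counts of genes and CCDC137 transcripts with the 7-base sequences, were chosen after the results they bear on had been seen.

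CCDC137 fell by 0.33 on the log2 scale while 6803 genes changed; a control library among the shCCDC137 libraries is argued against, since the highest of these lay at -7.86 shControl SD from the shControl mean. Scaling between libraries stays open for the size of the CCDC137 fall: 3 other scalings moved the CCDC137 value by at most 0.0121, but moved the median of all genes by as little (0.0121), so they hardly differ and do not test it. A scaling error moves all genes of a library alike, while 3416 genes were higher and 3387 lower. These counts argue against scaling as the source of calls in both directions. A match of the hairpin's seed to the 3′ UTRs of other transcripts could change many genes. The lowest z of 16319 sequences of 7 bases was -5.93, between the bounds set beforehand for presence (-8) and absence (-5), against a highest z of 4.50 and a lowest z of -3.68 on permuted fold changes. That sequence, GGGAGAA, occurred in 2672 genes and in 2 of 6 annotated transcripts of CCDC137, and the overlapping TGGGAGA in 0 of the 6, although a hairpin's seed should match its own target. An effect of lower CCDC137, whose protein was not analysed here, and an effect of the hairpin on other transcripts cannot be told apart, because the hairpin sequence was not used here.

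The ribosomal protein and respiratory chain lists, of short transcripts (median length 1857 and 1800.5 bases, against 3670 for all), rose, and the mitosis list (median GC content 42.5%) and the matrix list (4661 bases) fell, as a length and GC trend in the libraries could also give. Other lists went against such a trend in length, such as the NF-kB list (2287.5 bases, lower) and the lysosome list (3950 bases, higher). After the correction cytosolic ribosomal proteins kept a median of 0.187 (adjusted p 2.7e-09 by camera) and the nuclear-encoded respiratory chain 0.175 (adjusted p 7.2e-04), against 0.267 and 0.232 before. The mitosis list kept -0.407 (adjusted p 3.0e-14 by camera) and the matrix list -0.261 (adjusted p 7.8e-07). The trend is therefore argued against as the whole cause for the mitosis and matrix lists. Part of the size of 3 of the 4 lists went with the correction. The ribosomal protein and respiratory chain lists also met the bound set beforehand against the trend, by still passing with most of their median kept. Even so, the trend stays open for them. Their lengths are of the longest annotated transcript, which may exceed the one expressed, so the correction may be too small for them. An effect of the knockdown on these lists stays open, as untested.

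Genes of chromosome 20 were higher, with a median log2 fold change of 0.17 over 365 genes, 169 of them higher and 51 lower, beside chromosome 22 (0.11, 114 higher and 60 lower) and, toward lower values, chromosome 3 (-0.11, 276 of 758 genes lower). The length and GC trend is argued against for chromosome 20, since its median still lay 0.147 above that of all genes after the correction, against 0.167 before, while the medians of chromosomes 22 and 3 went to 0.059 and -0.067. Chance clustering along the genome remains, since 15.8% of 10000 rotations gave some chromosome a median as far from 0, although the rotations carry the chromosome 20 block itself along. A copy-number difference between the cell populations may also raise a whole chromosome, and the medians of the shorter and longer arm were 0.21 and 0.16. Its test cannot decide: the 0.0246 median of the chromosome 20 genes that did not pass (0.058 for chromosome 22) comes from genes picked for showing no shift, and DNA was not analysed here.

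Among the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 6803 genes, and the highest of the others gave 2. Each other split mixes shControl and shCCDC137 libraries on both sides, which puts the real difference into the spread within a side. Few calls follow by construction, so the low counts are no measure of false calls. With 10 splits the share cannot be under 0.05, so it decides nothing.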
